A study of Mus musculus with 29 samples.

How the data were processed

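The series holds bulk RNA sequencing of prefrontal cortex from mice at postnatal day 40. The mice were heterozygous for the K228E allele of Tbr1 (HT) or wild type (WT), of strain C57BL/6J and of both sexes, per the labels. HT mice received vehicle, fluoxetine or lithium, and WT mice received vehicle. The 29 libraries form 8 groups of genotype, treatment and sex with 3 or 4 libraries each. Libraries were made with a stranded poly(A) kit, per the labels' protocols, and the labels give the same batch for all of them.

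The deposited table gives a normalised signal per gene and library, which the authors made by dividing the read count of each gene by 1 size factor per library, as read from the values themselves. Every value in every library was a whole multiple of 1 step per library within a tolerance of 0.0001, and the steps differed between libraries, so whole reads could be recovered. In 3 HT fluoxetine libraries (females 1 and 2, male 3) the step lay close to 1. Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the build GRCm38 are named in the submitters' processing notes, without their role or order. The annotation release, the strand setting and the gene filter behind the table are not stated. Of 18240 Ensembl identifiers, 18227 matched a gene name and position in an annotation of GRCm38, from which all coordinates were taken. The recovered reads summed to 22.81 M to 31.71 M per library, and their number limits the precision of genes with few reads.

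Values were used on the authors' scale as log2(value + 1). Genes with a value of at least 10 in at least 3 libraries were tested, which left 17881. The test was limma 3.58.1 in R 4.3.3, with 1 mean per group for all 29 libraries (21 residual degrees of freedom), moderated with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences over both sexes are the mean of the female and the male difference. The comparisons were HT vehicle minus WT vehicle, each drug minus vehicle in HT, lithium minus fluoxetine in HT, each drug group of HT minus WT vehicle, the genotype difference and each drug minus vehicle in HT within each sex, the female minus male difference of the genotype and drug differences, and sex in WT vehicle. Errors on fold changes are standard errors (SE), and errors on group values are standard deviations (SD).

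Lists of genes for 37 cell types, pathways and complexes were written from general knowledge before the data were examined, and lists could share genes. They covered cortical neuron layers, interneurons, glia and vessels, neighbouring tissues, synapses and channels, activity and clock genes, stress and hormone responses, energy and protein metabolism, and the pathways named for each drug in the account of the results. Each was tested with camera from limma, which compares the list with all other tested genes, at a preset correlation between genes of 0.01, adjusted over the 37 lists of a comparison. The alternatives were camera with a correlation estimated from the data, and fry, which tests whether the genes of a list move on balance one way. Members of a list that passed were also counted with adjustment over the list alone.

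The choice of named genes was fixed before the data were examined. For genotype, fluoxetine and lithium over both sexes, the 10 higher and 10 lower genes with the smallest p were named among those past the threshold with a mean value of at least 50. The 5 with the smallest p were named where fewer than 3 passed. For the other comparisons 3 per direction were named in the same way, with up to 4 members of each list described and up to 10 genes called in a pair of comparisons. Gene models without an assigned name were counted and not named, except where the text says so. Tbr1 was named in every group.

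Differences that share the HT vehicle libraries are correlated even where nothing differs. The correlation across genes of a pair of such differences was therefore set beside 100 simulations without any group difference and beside the 36 ways of dividing the HT vehicle libraries between both differences. Added after the data were seen, the 37 genes with the smallest genotype p were chosen anew in 100 simulations, in the 36 ways of dividing the HT vehicle libraries and in the 36 ways of dividing the WT libraries into equal parts.

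The alternatives fixed at the start were quantile normalisation, rescaling by median ratios, pseudocounts of 0.5 and 10, no filter, a filter at 50, no intensity trend, robust moderation, library weights, only the groups compared, sex as an additive term, the replicate number as a block, a threshold of 0.1, and leaving out each library in turn. Chosen after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the means of the olfactory and striatal marker lists as covariates, and a fit without the 8 libraries in which either mean was more than 1 (log2) above the median of all libraries. The list tests of the 3 female minus male differences were also added then. The limma and camera tests were tried on simulated counts with known changes in 5 comparisons, which were genotype, fluoxetine and lithium over both sexes and genotype and fluoxetine in females. For the genotype comparison 49.3%, 73.1% and 78.8% of genes simulated with folds of 1.25, 1.5 and 2 were recovered, and 5.16% of calls were false. Each gene was drawn independently, without the variation between libraries that genes share, so these rates need not hold for the real calls.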

Results

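Prefrontal cortex from mice at postnatal day 40 was profiled by bulk RNA sequencing to compare carriers of the K228E allele of Tbr1 with wild-type mice, and carriers given a drug with carriers given vehicle. Tbr1 encodes a T-box transcription factor of deep-layer cortical neurons. Heterozygous mice (HT) received vehicle (3 females, 3 males), fluoxetine, a serotonin reuptake inhibitor (4 females, 4 males), or lithium, a mood stabiliser (3 females, 4 males). Wild-type mice (WT) received vehicle only (4 females, 4 males), so neither drug could be set against vehicle in WT. The labels give no dose, route or duration. The 29 libraries held between 22.81 M and 31.71 M reads in 18240 genes, and values are read counts normalised by a size factor per library. The most abundant gene, mt-Co1, took between 1.77% and 2.87% of the reads. Xist lay between 21485 and 38884 in libraries labelled female and at 16.2 or less in libraries labelled male, so sex labels and data matched in all 29.

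Tbr1 (ENSMUSG00000035033, chromosome 2, 61802930 to 61814114, GRCm38) was higher in HT than in WT mice under every treatment. Its normalised count was 2866 ± 445 (SD, n = 8) in WT vehicle, 4067 ± 392 (SD, n = 6) in HT vehicle, 4159 ± 590 (SD, n = 8) in HT fluoxetine and 4425 ± 321 (SD, n = 7) in HT lithium. The log2 fold change of HT vehicle against WT vehicle was 0.52 ± 0.090 (SE; limma adjusted p = 0.0164), a 1.43-fold difference. It was 0.54 ± 0.084 (adjusted p = 0.00504) for HT fluoxetine and 0.63 ± 0.087 (adjusted p = 0.000326) for HT lithium. All 6 HT vehicle libraries, from 3728 upwards, lay above all 8 WT libraries, of which the highest was at 3432. So did all 7 HT lithium libraries and 7 of 8 HT fluoxetine libraries, while HT fluoxetine female 1, at 2858.4, lay below 5 of the 8 WT libraries. Within HT, Tbr1 under fluoxetine differed from vehicle by 0.023 ± 0.090 (adjusted p = 0.969) and under lithium by 0.12 ± 0.094 (adjusted p = 0.644), less than the spread between replicates. The level of a transcript that carries a substituted codon does not by itself test which allele a mouse carries. The genotype call on Tbr1 was lost without HT vehicle female 1 or HT vehicle male 3, with adjusted p up to 0.0963, while its log2 fold change stayed between 0.47 and 0.57 over 47 other settings.

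**Figure D1:**
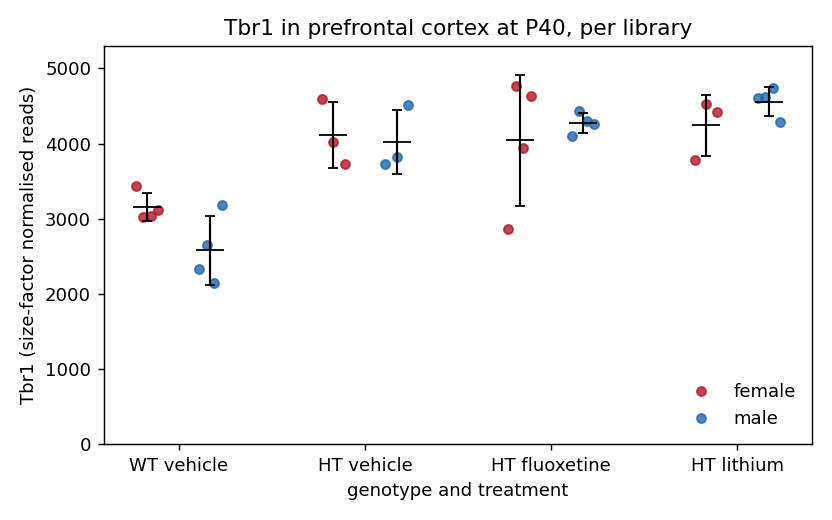
Normalised read counts of Tbr1 in each of the 29 libraries, by genotype and treatment on the horizontal axis, with females in red and males in blue; bars give the mean and SD of each group. The HT vehicle libraries lie between 3728 and 4593 and the WT vehicle libraries between 2151 and 3432.

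Prefrontal dissections can hold tissue of neighbouring regions, and markers of olfactory areas and of striatum differed widely between libraries. The mean of the striatal markers, centred on all libraries, was 0.42 ± 0.977 (SD, n = 8) in HT fluoxetine, -0.33 ± 0.208 (SD, n = 6) in HT vehicle, -0.069 ± 0.530 (SD, n = 7) in HT lithium and -0.11 ± 0.641 (SD, n = 8) in WT vehicle (log2). The olfactory marker mean was -0.71 ± 1.338 (SD) in HT lithium, 0.37 ± 0.596 in HT vehicle, -0.054 ± 0.969 in HT fluoxetine and 0.40 ± 1.030 in WT vehicle. In 8 of the 29 libraries either mean lay more than 1 above the median of all libraries. They were HT fluoxetine female 1 and WT vehicle male 3 for olfactory markers, and HT fluoxetine female 2, HT fluoxetine males 1 and 2, HT lithium female 2 and WT vehicle females 1 and 3 for striatal markers. None of the 6 HT vehicle libraries was among them. Low means were not counted, so the fit without these 8 keeps HT lithium males 3 and 1 and HT fluoxetine female 4, whose olfactory means lay at -2.6, -2.21 and -1.11 from the median.

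**Figure D2:**
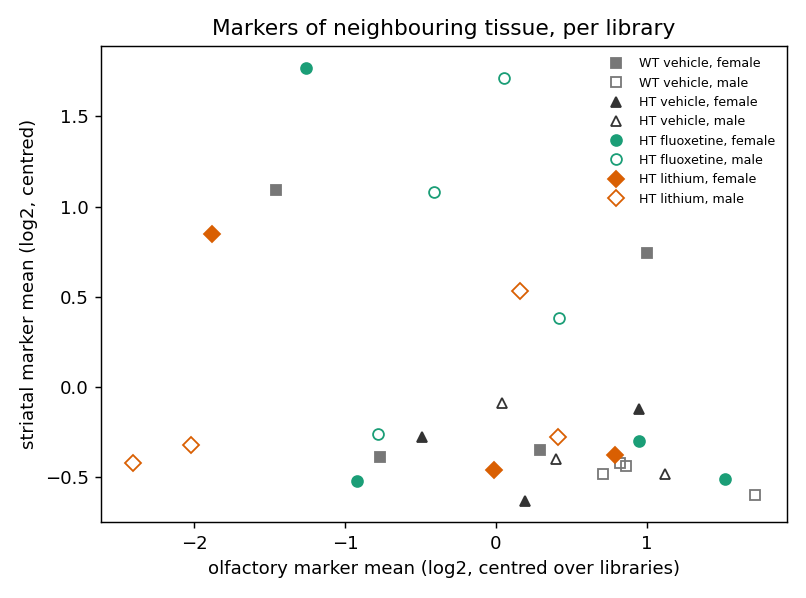
Mean log2 value of the olfactory markers (horizontal) and of the striatal markers (vertical) in each of the 29 libraries, each centred on the mean of all libraries, coloured by genotype and treatment. HT fluoxetine female 2 (1.77) and HT fluoxetine male 2 (1.71) lie highest on the striatal axis, and WT vehicle male 3 (1.72) farthest to the olfactory side.

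The genotype comparison asked how carriers differ from wild-type mice without a drug. In HT vehicle against WT vehicle, 29 genes rose and 8 fell (limma), 34 of them with an assigned name. The highest-ranked gene was Whrn, which encodes the PDZ scaffold whirlin (log2 fold change 0.37 ± 0.053 SE, 1.29-fold, adjusted p = 0.0039). Whrn lay at 1352 ± 59.1 (SD, n = 6) in HT vehicle and 1052 ± 105 (SD, n = 8) in WT. Adra1d, an alpha-1 adrenergic receptor, rose by 0.42 ± 0.077 (adjusted p = 0.0193), the muscarinic receptor gene Chrm4 by 0.39 ± 0.075 (adjusted p = 0.0274) and the postsynaptic adhesion gene Lrrtm1 by 0.21 ± 0.041 (adjusted p = 0.0298). The other named genes that rose were the proprotein convertase gene Pcsk4 (1.54-fold), the lysosomal glucosidase gene Gaa (1.22-fold), Plcxd2 (1.18-fold), the Notch-ligand relative Dlk2 (1.25-fold) and the astrocytic folate enzyme gene Aldh1l1 (1.13-fold), besides Tbr1. Cebpd, a transcription factor of inflammatory responses, fell most, by -0.51 ± 0.107 (adjusted p = 0.0398). Gja1, which encodes the astrocytic gap-junction protein connexin 43, fell by 0.19 on the log2 scale (adjusted p = 0.0313). Ldlrad3, the formin gene Fmnl2, Cpne3, the TGF-beta receptor gene Tgfbr2, the fatty-acid oxidation gene Decr1 and the double-stranded RNA receptor gene Tlr3 also fell, to between 0.818 and 0.873 of the WT level. Dlk2 overlaps Abcc10 on the opposite strand, and whether the counting used strand is not stated, so its value is uncertain. Chrm4, Ldlrad3 and Fmnl2 lie on chromosome 2 within 50 Mb of Tbr1. Their differences were not told apart from a donor strain segment around Tbr1, which is taken up below and stays open. The tests on recovered reads gave 23 higher and 6 lower genes with edgeR and 138 and 74 with DESeq2. The count was 6 without the 8 libraries with high olfactory or striatal markers, and leaving out 1 library took it from 2 (without HT vehicle female 1) to 176 (without WT vehicle male 4). Whrn passed in each of 47 other settings, whereas Tlr3 lost its call in 33, Decr1 in 26 and Tgfbr2 in 25.

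Clock genes were higher as a group in HT vehicle mice. The list of 19 circadian clock genes had a median log2 fold change of 0.091 with 14 members positive (camera adjusted p = 5.56e-06; adjusted p = 0.128 with an estimated correlation). Nr1d1 (0.28 ± 0.059, adjusted p = 0.038) and Bhlhe40 (0.27 ± 0.057, adjusted p = 0.0401), both transcriptional repressors of the clock, rose. Per2 stood at 0.32 ± 0.073 (adjusted p = 0.0583) and Per1 at 0.19 ± 0.052 (adjusted p = 0.114), and 8 members were higher when adjusted over the list alone. Immediate early genes, which neuronal activity induces, had a median of 0.063 with 23 of 33 positive (camera adjusted p = 0.0444; adjusted p = 0.781 with an estimated correlation). None of the 33 was called over all genes, and 2 were higher adjusted over the list alone. Per1 and Ier5 (0.18 ± 0.055) led that list. The call on immediate early genes was lost with the olfactory and striatal marker means as covariates (adjusted p = 0.0989). It was also lost without any 1 of HT vehicle females 2 and 3, HT vehicle males 1 and 2, WT vehicle female 2 and WT vehicle males 1, 2 and 4 (adjusted p between 0.0518 and 0.326).

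Marker lists of the cortical layers were each tested for genotype. Layer 5 markers were higher by camera (median 0.14, 11 of 17 positive, adjusted p = 0.0444; adjusted p = 0.464 with an estimated correlation), with Tshz2 called (0.33 ± 0.072, adjusted p = 0.0487). Fezf2, which specifies subcerebral projection neurons, stood at 0.39 ± 0.119 (adjusted p = 0.15). In the same list 5 members were higher and Npr3 (-0.29 ± 0.080) was lower adjusted over the list alone. The layer 5 call was lost without HT vehicle female 2, HT vehicle male 3, WT vehicle female 4 or WT vehicle male 1 (adjusted p between 0.0572 and 0.179). Upper layer markers were higher by camera (median 0.083, 15 of 18 positive, adjusted p = 0.0062; adjusted p = 0.393 with an estimated correlation), of which Plcxd2 was called. Layer 6 and 6b markers, the layers where Tbr1 is most expressed, had a median of -0.082 with 15 of 19 negative, and camera did not call them (adjusted p = 0.152). The 20 Tbr1-linked genes split evenly, 10 positive and 10 negative (adjusted p = 0.135). Lists of interneurons (adjusted p = 0.433), glutamate receptors and postsynaptic density (0.0554), presynaptic vesicles (0.0554), GABA receptors and inhibitory synapses (0.973) and voltage gated potassium and sodium channels (0.201) were not called by camera.

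Markers of glia, vessels and meninges were lower as lists in HT vehicle mice. Meningeal and fibroblast markers had a median of -0.18 with 15 of 16 negative (camera adjusted p = 5.56e-06; adjusted p = 0.464 with an estimated correlation). Endothelial and mural markers had a median of -0.094 with 23 of 25 negative (adjusted p = 2.43e-05; adjusted p = 0.393 with an estimated correlation), and Tek stood at -0.23 ± 0.059 (adjusted p = 0.0911). The medians were -0.12 for microglia, -0.12 for oligodendrocyte precursors, -0.13 for myelin genes and -0.059 for astrocytes. Their camera adjusted p were 3.88e-05, 0.00432, 0.00475 and 0.00475. With an estimated correlation the adjusted p = 0.393, 0.393, 0.781 and 0.393, respectively. The myelin call was lost with the marker covariates (adjusted p = 0.0597), without the 8 libraries with high markers (0.131), and without HT vehicle female 3, HT vehicle male 1, WT vehicle female 1 or WT vehicle male 4 (between 0.0643 and 0.445). Astrocyte markers went both ways: Gja1 fell, Aldh1l1 rose, and adjusted over the list alone Aqp4 (-0.27 ± 0.073) and F3 (-0.14 ± 0.040) were also lower. The 13 mitochondrially encoded genes were all negative (median -0.20, camera adjusted p = 6.08e-05; adjusted p = 0.393 with an estimated correlation). Serotonin receptor and transport genes had a median of -0.093, led by Maoa (-0.12 ± 0.040) and Htr2a (-0.19 ± 0.065), with camera adjusted p = 0.0203 (adjusted p = 0.135 with an estimated correlation); without HT vehicle male 2 that call was lost (0.0615). Ribosomal protein genes were lower (median -0.024, adjusted p = 0.0203) and chromatin regulators higher (median 0.032, adjusted p = 0.0455), with adjusted p = 0.781 for both with an estimated correlation. The ribosomal call was lost without HT vehicle females 1 or 2, HT vehicle males 1 or 3, WT vehicle female 3 or WT vehicle male 1 (adjusted p between 0.087 and 0.194). The chromatin call was lost without HT vehicle female 2, HT vehicle males 1 or 3, WT vehicle females 1 or 4 or WT vehicle males 1 or 2 (between 0.0572 and 0.615). Markers of striatum (median -0.22, adjusted p = 0.152), choroid plexus (-0.14, 0.185), thalamus (-0.13, 0.101), olfactory areas (-0.068, 0.593) and blood (-0.087, 0.356) were not called by camera. Camera called 14 of 37 lists in all, none of them with an estimated correlation, and 27 of 100 splits of the same libraries gave as many.

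Within each sex limma and edgeR called no gene for genotype, while DESeq2 did. In females limma called 0 genes, with 1333 at an unadjusted p under 0.05 where 894 are expected, edgeR 0, and DESeq2 20 higher and 14 lower. The smallest adjusted p was that of Adra1d (0.61 ± 0.109, adjusted p = 0.118). In males limma called 0 genes with 1990 at an unadjusted p under 0.05, edgeR 0, and DESeq2 24 higher and 12 lower. In males Whrn stood at 0.43 ± 0.075 (adjusted p = 0.0891), Mrpl1 at -0.35 ± 0.072 (adjusted p = 0.137) and Tbr1 at 0.65 ± 0.128 (adjusted p = 0.134), and Tbr1 in females stood at 0.38 ± 0.128 (adjusted p = 0.43). The test of the female minus male difference called 0 genes (limma; 1001 at an unadjusted p under 0.05; edgeR 0; DESeq2 1), with Mrpl1 first (0.48 ± 0.102, adjusted p = 0.847). In females the glucocorticoid responsive genes were lower by camera (median -0.14, adjusted p = 0.0243; adjusted p = 0.585 with an estimated correlation), led by Sgk1 (-0.53 ± 0.142). That call was lost without HT vehicle female 1 (adjusted p = 0.17) or WT vehicle female 4 (0.056). In males the Tbr1-linked genes were higher (median 0.12, 17 of 20 positive, adjusted p = 0.0193; adjusted p = 0.576 with an estimated correlation). That call was lost without HT vehicle males 1 or 3 or WT vehicle male 1 (adjusted p = 0.0842, 0.127 and 0.178). No list call within a sex held with an estimated correlation. The male count was 12 without HT vehicle male 2 and, rounded, 2.3e+02 without WT vehicle male 4.

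Fluoxetine was set against vehicle within HT mice to ask what the drug changes in carriers. Limma called 0 genes over both sexes (n = 8 and 6), with 1397 at an unadjusted p under 0.05 where 894 are expected, edgeR called 0 and DESeq2 4 higher and 2 lower. Aldh1l1, which had risen with genotype, had the smallest adjusted p, at -0.18 ± 0.033 (SE; adjusted p = 0.296). Its count was 1657 ± 46.7 (SD) under fluoxetine, 1874 ± 106 (SD) under vehicle and 1654 ± 51.7 (SD) in WT. The other genes with the smallest p, none past the threshold, were Tpm4 (0.18 ± 0.039), Scoc (0.19 ± 0.043), Fndc9 (0.63 ± 0.146), Cop1 (0.15 ± 0.035) and Rbm34 (0.20 ± 0.048) above 0, and Dpysl4 (-0.16 ± 0.034), Jag2 (-0.15 ± 0.037), Ldhd (-0.22 ± 0.056) and Rrp9 (-0.15 ± 0.039) below 0, each with adjusted p = 0.402. Camera called 8 lists, and none of the calls held with an estimated correlation (smallest adjusted p = 0.143).

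Among the lists for fluoxetine, the striatal markers stood highest. All 19 were positive (median 0.61, camera adjusted p = 2.45e-09; adjusted p = 0.832 with an estimated correlation), led by Lrrc10b (1.27 ± 0.369), the 1 member higher when adjusted over the list alone, and the adenosine receptor gene Adora2a (1.34 ± 0.565). The marker mean was high in HT fluoxetine female 2 and males 1 and 2. With both marker means as covariates 3 lists were called, and without the 8 libraries with high markers 5. Myelin genes were positive in 27 of 28 (median 0.18, adjusted p = 9.01e-06; adjusted p = 0.996 with an estimated correlation), with Ugt8a at 0.26 ± 0.126. Layer 6 markers were higher (median 0.068, adjusted p = 0.0394; adjusted p = 0.996 with an estimated correlation). With the marker covariates the medians of myelin, layer 6 and striatal lists were -0.046, -0.062 and -0.018 (adjusted p = 0.444, 0.779 and 0.897). The layer 6 call was also lost without HT fluoxetine female 2, HT fluoxetine males 2 or 4, HT vehicle female 3 or HT vehicle males 1 or 2 (adjusted p between 0.106 and 0.506). Immediate early genes were lower (median -0.13, 24 of 33 negative, adjusted p = 0.00087; adjusted p = 0.996 with an estimated correlation), with the activity-induced Arc at -0.31 ± 0.093 and Junb at -0.24 ± 0.095. This call was lost with the marker covariates (median -0.023, adjusted p = 0.708), without HT fluoxetine female 2 (-0.065, 0.115) and without HT vehicle male 2 (-0.098, 0.0686). Serotonin receptor and transport genes, the pathway of the drug's target, had a median of 0.049 with 13 of 18 positive (adjusted p = 0.0143; adjusted p = 0.143 with an estimated correlation), led by Htr1b (0.33 ± 0.137). The serotonin call was lost without HT vehicle male 2 (adjusted p = 0.0686) and without the libraries with high markers (0.0615). Mitochondrially encoded genes (median 0.15, adjusted p = 0.000886) and endoplasmic reticulum chaperones (median 0.057, adjusted p = 0.000258) were higher, and chromatin regulators lower (median -0.033, adjusted p = 0.00919). With an estimated correlation their adjusted p = 0.937, 0.937 and 0.996. The chromatin call was lost with the marker covariates (adjusted p = 0.103) and without HT fluoxetine female 2, HT fluoxetine male 4, HT vehicle female 2 or HT vehicle males 1 or 3 (between 0.0621 and 0.562). Neurotrophin and plasticity genes were not called (median 0.019, adjusted p = 0.569).

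Lithium was set against vehicle within HT mice in the same way. Limma called 0 genes over both sexes (n = 7 and 6), with 2030 at an unadjusted p under 0.05 where 894 are expected, edgeR 0, and DESeq2 24 higher and 8 lower. Abcc10, a transporter gene that overlaps Dlk2, had the smallest adjusted p (-0.27 ± 0.049 SE, adjusted p = 0.178). Next came Dpysl4 (-0.17 ± 0.035), the RNA polymerase subunit gene Polr2a (-0.17 ± 0.035) and the zinc transporter gene Slc30a9 (0.14 ± 0.029), each with adjusted p = 0.213. The mitochondrial gene mt-Nd6 (0.55 ± 0.119), Synj2bp (0.18 ± 0.040), Dnaja1 (0.16 ± 0.036), Nr6a1 (0.28 ± 0.062), Vars2 (-0.15 ± 0.035) and Aldh1l1 (-0.15 ± 0.035) had adjusted p = 0.214. Reads of mt-Nd6 and its neighbours can also match nuclear copies, so their values are uncertain.

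Endoplasmic reticulum stress and chaperone genes had the smallest camera p of the lists under lithium. Of 31 genes, 27 were positive (median 0.12, camera adjusted p = 7.12e-13; adjusted p = 0.344 with an estimated correlation; fry adjusted p = 0.0438). None was called over all genes, whereas 15 were higher adjusted over the list alone. They included Dnajc3 (0.17 ± 0.044), the disulfide isomerase gene Pdia3 (0.14 ± 0.037) and the stress transcription factor gene Xbp1 (0.17 ± 0.046). Proteasome subunits (median 0.042, adjusted p = 0.0038), myelin genes (0.15, 0.00307), mitochondrially encoded genes (0.096, 0.0317) and cholesterol synthesis genes (0.045, 0.0487) were also higher, with adjusted p = 0.777, 0.777, 0.777 and 0.799 with an estimated correlation. The proteasome call was lost without HT vehicle male 1 (adjusted p = 0.102). The myelin call was lost with the marker covariates (median 0.045, adjusted p = 0.154) and without HT lithium female 2, HT vehicle female 3 or HT vehicle male 1 (between 0.0698 and 0.23). The mitochondrial call was lost with the covariates (0.285) and without HT lithium female 2, HT lithium male 3, HT vehicle female 2 or HT vehicle male 3 (between 0.0758 and 0.211). The cholesterol call was lost with the covariates (0.798) and without any 1 of HT lithium females 2 and 3 and males 1 and 2, HT vehicle females 2 and 3 and male 1, HT fluoxetine female 2 and males 1, 3 and 4, WT vehicle female 3 and all 4 WT vehicle males (between 0.0508 and 0.566). Olfactory markers (median -1.01, adjusted p = 0.0038), interferon and antigen presentation genes (-0.092, 0.0139), chromatin regulators (-0.037, 0.0119) and astrocyte markers (-0.034, 0.0257) were lower, each with adjusted p = 0.777 with an estimated correlation. The olfactory call was lost without HT lithium female 2 or HT vehicle female 2 (adjusted p = 0.0758 and 0.0532). The olfactory mean is itself a covariate in the fit with marker covariates, which therefore cannot test that list. The interferon call was lost without HT lithium female 3, HT lithium male 2 or HT vehicle male 2 (between 0.0501 and 0.232), and the astrocyte call without HT lithium females 2 or 3 or HT lithium male 2 (between 0.0538 and 0.0758). The chromatin call was lost without HT lithium female 2, HT lithium male 3, HT vehicle female 2 or HT vehicle males 1 or 3 (between 0.0519 and 0.263). With the covariates the last 3 had adjusted p = 0.0569, 0.118 and 0.611. Inositol phosphate metabolism, which lithium inhibits, and Wnt target genes were not called (medians 0.025 and -0.001, adjusted p = 0.346 and 0.361). Camera called 2 lists with the olfactory and striatal marker means as covariates, 4 without the 8 libraries with high markers and 3 without HT lithium female 2.

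Lithium and fluoxetine were compared with each other in HT mice (n = 7 and 8). Limma called 0 genes, with 626 at an unadjusted p under 0.05, fewer than the 894 expected, edgeR 0 and DESeq2 1 higher and 1 lower. The smallest p were those of Nr6a1 (0.24 ± 0.058 SE), Jdp2 (0.20 ± 0.049), Zbtb16 (0.33 ± 0.091), Mmp14 (-0.28 ± 0.069), Abcc10 (-0.16 ± 0.046) and Mro (-0.23 ± 0.069), each with adjusted p = 0.985. Endoplasmic reticulum chaperones were higher under lithium than under fluoxetine (median 0.057, 28 of 31 positive, camera adjusted p = 1.54e-07; adjusted p = 0.716 with an estimated correlation), a call lost without the libraries with high markers (adjusted p = 0.06). Meningeal markers (median -0.15, 16 of 16 negative, adjusted p = 1.29e-06) and striatal markers (median -0.41, adjusted p = 1.82e-06) were lower, both with adjusted p = 0.716 with an estimated correlation. Clock genes (0.035) and cholesterol synthesis genes (0.034) were higher, and olfactory (-0.63), astrocyte (-0.037) and ribosomal (-0.022) lists lower, each with camera adjusted p = 0.0133 and adjusted p = 0.716 with an estimated correlation. Without the libraries with high markers only the meningeal call of these 8 was kept (median -0.13, adjusted p = 0.00312), and the medians were -0.053 for striatal markers (adjusted p = 0.338), 0.032 for clock genes (0.338), -0.029 for the cholesterol list (0.242), -0.203 for olfactory markers (0.574), 0.004 for astrocytes (0.637) and -0.004 for ribosomal genes (0.648). With the marker covariates the striatal (adjusted p = 0.352), olfactory (0.581), clock (0.0541) and ribosomal (0.305) calls were lost and the other 4 kept. The striatal call was lost without HT fluoxetine female 2 (adjusted p = 0.0758) and the clock call without HT fluoxetine female 3 (0.0518). The cholesterol call was lost without HT fluoxetine female 1, HT fluoxetine male 1, HT lithium females 2 or 3 or HT lithium male 2 (between 0.0741 and 0.709), and the astrocyte call without HT fluoxetine male 1 or the same 3 lithium libraries (between 0.0741 and 0.0937). The ribosomal call was lost without HT fluoxetine females 1 or 2, HT fluoxetine male 4 or those 3 libraries (between 0.0924 and 0.74). The olfactory call was lost without HT fluoxetine females 1 or 3, HT fluoxetine male 4, HT lithium female 2 or HT lithium males 1 or 3 (between 0.0613 and 0.352).

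Treated carriers were also compared with untreated wild-type mice, which combines the genotype and the drug. In HT fluoxetine against WT vehicle (n = 8 and 8) 26 genes rose and 8 fell (limma; edgeR 24 and 8, DESeq2 75 and 21). Besides Tbr1, the calcium-binding protein gene Necab1 (0.30 ± 0.045 SE, adjusted p = 0.00439) and the endothelial transcription factor gene Sox18 (0.46 ± 0.076, adjusted p = 0.00839) rose. The stress-response gene Ddit4 (-0.37 ± 0.059, adjusted p = 0.00666), Cebpd (-0.58 ± 0.099, adjusted p = 0.00839) and Tgfbr2 (-0.20 ± 0.040, adjusted p = 0.0264) fell. In HT lithium against WT vehicle (n = 7 and 8) 238 rose and 102 fell (limma; edgeR 211 and 93, DESeq2 407 and 181). Per2 (0.54 ± 0.070), the glycolytic regulator gene Pfkfb3 (0.36 ± 0.048) and the insulin signalling gene Irs2 (0.34 ± 0.046) rose, each with adjusted p = 0.000326. Cep85l (-0.35 ± 0.051, adjusted p = 0.000574), Cebpd (-0.68 ± 0.103, adjusted p = 0.000729) and the metalloproteinase gene Mmp14 (-0.44 ± 0.069, adjusted p = 0.00102) fell. These 6 genes of the lithium comparison passed in all 47 other settings. The fluoxetine count was 0 when only the 4 compared groups were fitted, where Tbr1 had adjusted p = 0.0578, and 5 without the libraries with high markers, where the lithium count was 42.

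Clock and chaperone genes were higher by camera in treated carriers than in wild-type mice. In HT lithium the clock list had a median of 0.12 with 16 of 19 positive (camera adjusted p = 4.02e-08), and it was the 1 list call in any comparison that held with an estimated correlation (adjusted p = 0.0472). Per2, Bhlhe40 (0.40 ± 0.055, adjusted p = 0.000326) and Cry2 (0.12 ± 0.031, adjusted p = 0.0372) rose, and 10 members were higher adjusted over the list alone. In HT fluoxetine the clock median was 0.095 (adjusted p = 6.9e-07; adjusted p = 0.0875 with an estimated correlation), with Bhlhe40 (0.28 ± 0.053) and Per2 (0.34 ± 0.067) called. Of the 31 chaperone genes 30 were positive in HT lithium (median 0.12, adjusted p = 1.95e-15; adjusted p = 0.084 with an estimated correlation). Among them 9 were called, such as Hyou1 (0.21 ± 0.033), Hspa5 (0.28 ± 0.047) and Pdia4 (0.29 ± 0.055), and 20 were higher adjusted over the list alone. In HT fluoxetine their median was 0.073 (adjusted p = 1.91e-09; adjusted p = 0.282 with an estimated correlation), with Hyou1 called (0.15 ± 0.032).

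Other lists also differed by camera between treated carriers and wild-type mice. In HT lithium astrocyte markers were lower (median -0.12, 20 of 23 negative, camera adjusted p = 6.77e-07; adjusted p = 0.084 with an estimated correlation), with F3 (-0.17 ± 0.038) and Gja1 (-0.13 ± 0.035) called and 14 lower adjusted over the list alone. Meningeal markers were all 16 negative (median -0.28, adjusted p = 3.18e-09; adjusted p = 0.322 with an estimated correlation), with Igfbp2 called (-0.32 ± 0.073). Layer 5 markers were higher (median 0.17, adjusted p = 0.000623; adjusted p = 0.197 with an estimated correlation), with Trib2 (0.27 ± 0.051), Fezf2 (0.60 ± 0.115) and Tshz2 (0.29 ± 0.070) called. Wnt target genes were lower (median -0.12, adjusted p = 0.0279; adjusted p = 0.308 with an estimated correlation), with the receptor gene Fzd7 called (-0.35 ± 0.075). The Wnt call was lost with the marker covariates (adjusted p = 0.069) and without WT vehicle female 4 (0.0771) or WT vehicle male 1 (0.0623). Extracellular matrix and perineuronal net genes were lower (median -0.10, adjusted p = 0.00722; adjusted p = 0.391 with an estimated correlation), although the inhibitor gene Timp2 rose (0.14 ± 0.025). Interferon and antigen presentation genes were lower (median -0.14, adjusted p = 6.78e-05; adjusted p = 0.362 with an estimated correlation), with H2-D1 called (-0.20 ± 0.045). Interneuron markers were lower (median -0.18, adjusted p = 0.0434; adjusted p = 0.473 with an estimated correlation). With the marker covariates their median was 0.020 (adjusted p = 0.874), and the call was lost without HT fluoxetine male 1, HT lithium female 2, HT lithium males 1 or 3, WT vehicle female 3 or WT vehicle males 2, 3 or 4 (between 0.052 and 0.127). Olfactory markers, whose median was -1.10 (adjusted p = 0.00087; adjusted p = 0.466 with an estimated correlation), moved with this comparison. Camera called 15 lists in HT fluoxetine, several of them the same. Astrocyte markers (median -0.081, camera adjusted p = 2.26e-05; adjusted p = 0.282 with an estimated correlation), meningeal markers (-0.138, 0.00022; adjusted p = 0.486 with an estimated correlation) and interferon and antigen presentation genes (-0.067, 0.000565; adjusted p = 0.464 with an estimated correlation) were lower, and layer 5 markers higher (0.155, 0.00307; adjusted p = 0.377 with an estimated correlation). Extracellular matrix genes were lower (-0.051, 0.0126; adjusted p = 0.464 with an estimated correlation), a call lost without HT fluoxetine male 4 (0.111). Striatal markers were higher in HT fluoxetine (0.396, 1.43e-05; adjusted p = 0.465 with an estimated correlation), with a median of -0.024 with the marker covariates (adjusted p = 0.78).

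The 37 genes called for genotype were followed in treated carriers. All 37 had the same sign against WT under both drugs. These comparisons share the WT libraries, and the 37 genes with the smallest genotype p in simulations without group differences had the same sign under both drugs in 31.3 genes on average and in all 37 in 8 of 100 simulations. With the WT libraries divided between both comparisons and the genes chosen anew, 31.6 of 37 had the same sign under fluoxetine and 32.6 under lithium (means of 36 divisions), where equal chances of either sign give 18.5. Of the 37 genes, 13 were called against WT under fluoxetine and 22 under lithium. Their median difference, signed by genotype, was 0.28 with vehicle, 0.20 with fluoxetine and 0.20 with lithium, against 0.32, 0.12 and 0.13 in the simulations, where the genes were likewise chosen for the vehicle difference. The genotype and fluoxetine comparisons against WT shared 11 higher genes (Tbr1, Gaa, Plcxd2, Krt77, Irs2, C2cd2l, Chrm4, Coro1c, Bhlhe40, Lrrtm1 and a gene model) and 2 lower ones (Cebpd and Tgfbr2), where independence would give 0.0422 and 0.00358. The genotype and lithium comparisons shared 17 higher and 5 lower genes, the latter Ldlrad3, Cebpd, Tgfbr2, Fmnl2 and Gja1, where independence would give 0.386 and 0.0456. As many genes taken by p shared 2.01 higher and 0.23 lower genes for fluoxetine, and 8.17 and 1.68 for lithium, on average in the simulations, and 5.22 and 0.028, and 9.78 and 1.25, with divided WT libraries. For 31 of the 37 genes the drug difference had the opposite sign to genotype for either drug, and 0 were called for either drug (limma). The simulations gave 36.0 on average, but they hold no genotype difference and so do not set the level for genes with a real one. The genotype and drug differences both hold the HT vehicle libraries on which the genes were chosen. With these libraries divided and the genes chosen anew, 22.1 of 37 had the opposite sign under fluoxetine (10 to 30 over 36 divisions) and 21.1 under lithium (10 to 31).

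**Figure D3:**
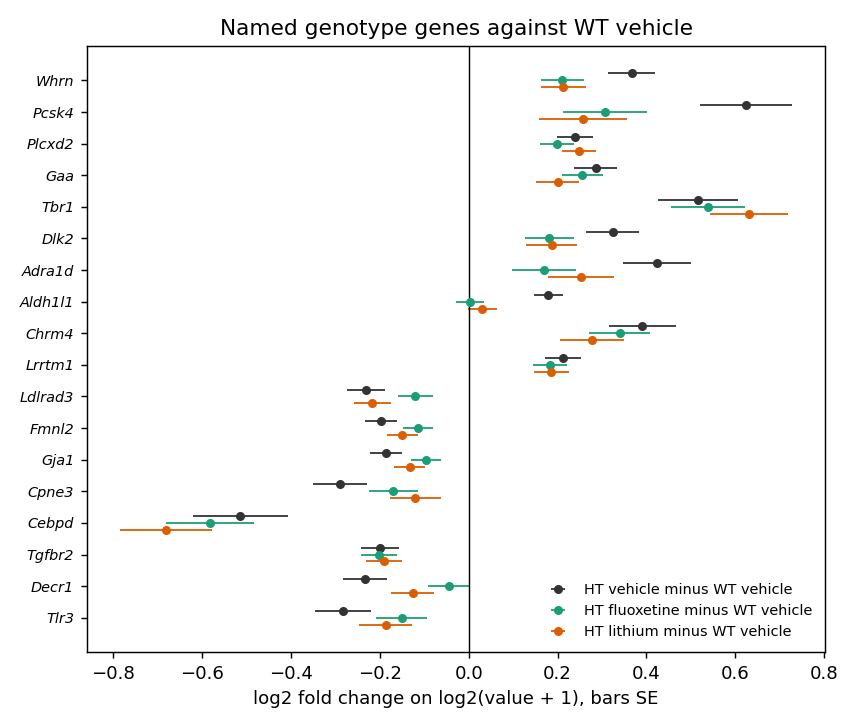
Log2 fold changes against WT vehicle, with SE, of the 18 genes named for genotype, in HT vehicle, HT fluoxetine and HT lithium mice. Tbr1 stands at 0.52, 0.54 and 0.63, and Cebpd at -0.51, -0.58 and -0.68.

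Whether a drug difference runs against the genotype difference was examined across genes, as 1 of 3 such relations. Across 17881 genes, which are not independent replicates, the fluoxetine and genotype differences had a correlation of -0.54 and the lithium and genotype differences one of -0.43. Both differences contain the HT vehicle libraries, with opposite sign. Simulations without group differences gave means of -0.57 and -0.53, and the covariances were -0.0205 and -0.018 against -0.0207 and -0.02 simulated. When the HT vehicle libraries were divided between both differences, the correlations averaged -0.018 and 0.017 over 36 divisions. Over the 37 genotype genes the correlations were -0.70 and -0.68, against -0.90 and -0.90 in simulations that chose the genes anew, and -0.037 and -0.14 with divided libraries and genes chosen anew. No reversal beyond the shared libraries and the choice of genes was detectable in these values. The fluoxetine and lithium differences had a correlation of 0.61, against 0.55 in simulations and 0.096 with divided libraries, and a covariance of 0.0256 against 0.021 simulated.

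Fluoxetine differed between the sexes of HT mice. The test of the female minus male difference called 1 gene higher and 18 lower (limma; edgeR 1 and 19, DESeq2 56 and 142), 17 of them with an assigned name. Genes of oxidative phosphorylation led it: Ndufa1 (-0.76 ± 0.113 SE), Cox7b (-0.56 ± 0.084) and Ndufa2 (-0.71 ± 0.107) were lower, each with adjusted p = 0.00336. Cox7b lay at 2910 ± 155 (SD, n = 4) in fluoxetine females and 3796 ± 298 (SD, n = 3) in vehicle females, and at 3771 ± 151 (SD, n = 4) and 3329 ± 109 (SD, n = 3) in the corresponding males. The 1 higher gene was the protocadherin gene Pcdhga2 (0.98 ± 0.184, adjusted p = 0.0224), which shares exons with its cluster, so its count is uncertain. The count was 4 without HT vehicle female 3, 1 when only the compared groups were fitted, and 71 without the libraries with high markers.

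In females alone 5 genes fell with fluoxetine and 0 rose (limma; edgeR 0 and 8, DESeq2 51 and 87; 2124 at an unadjusted p under 0.05). They were Cox7b (-0.38 ± 0.059 SE, adjusted p = 0.0143), Ndufa1 (-0.46 ± 0.080, adjusted p = 0.0354), Nprl2 (-0.28 ± 0.050, adjusted p = 0.0354), Uqcr10 (-0.46 ± 0.083, adjusted p = 0.0354) and Tcap (-0.63 ± 0.118, adjusted p = 0.048), the last chosen after its value was seen. Bclaf1 (0.23 ± 0.045), Dgkb (0.28 ± 0.058) and Syncrip (0.26 ± 0.054) had adjusted p = 0.0501. The count was 0 without HT fluoxetine female 4 and without HT vehicle female 3, and 87 without HT fluoxetine female 1. In males limma called 0 genes (1788 at an unadjusted p under 0.05; edgeR 0, DESeq2 1), with Pcdhga2 (-0.69 ± 0.130, adjusted p = 0.279) and Psmb4 (0.22 ± 0.050, adjusted p = 0.291) among the smallest p.

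Oxidative phosphorylation, ribosomal and proteasome genes moved in opposite directions in females and males. Of 77 nuclear oxidative phosphorylation genes, 70 were negative in females (median -0.14, camera adjusted p = 2.69e-21; adjusted p = 0.433 with an estimated correlation) and 76 positive in males (median 0.14, adjusted p = 2.24e-25; adjusted p = 0.297 with an estimated correlation). Their female minus male median was -0.26 with 76 negative (adjusted p = 7.07e-38; adjusted p = 0.0812 with an estimated correlation; fry adjusted p = 0.00293). In that test 6 members were called and 51 were lower adjusted over the list alone. Ribosomal protein genes (median -0.26, 77 of 80 negative, adjusted p = 1.82e-30) and proteasome genes (median -0.15, 32 of 34 negative, adjusted p = 2e-13) were lower too, each with adjusted p = 0.19 with an estimated correlation. Ribosomal genes had a median of -0.137 in females (adjusted p = 2.14e-17; adjusted p = 0.645 with an estimated correlation) and 0.125 in males (adjusted p = 1.79e-19; adjusted p = 0.308 with an estimated correlation). Proteasome genes had -0.05 in females (adjusted p = 0.000187; adjusted p = 0.857 with an estimated correlation) and 0.099 in males (adjusted p = 2.37e-13; adjusted p = 0.297 with an estimated correlation). Random lists matched to the oxidative phosphorylation genes on length, GC content and abundance had a female minus male median of -0.14, and 0 of 1000 were as low as -0.26. Their pool left out the ribosomal, proteasome and mitochondrially encoded lists, of which the ribosomal and proteasome genes were themselves lower. Genes drawn at random also need not vary together as those of the list do, so 0 of 1000 is no measure of chance. Rpl38 (-0.63 ± 0.126), Psmb3 (-0.43 ± 0.076) and Psmb4 (-0.34 ± 0.071) were called, and ribosomal protein genes have many processed pseudogenes that can share their reads. Chromatin regulators were positive in 46 of 46 (median 0.18, adjusted p = 2e-13) and autism risk genes in 51 of 56 (median 0.15, adjusted p = 3.57e-09), each with adjusted p = 0.326 with an estimated correlation. Chd8, a gene of both lists, stood at 0.21 ± 0.065. Matched random lists were drawn for the oxidative phosphorylation genes only. A part of transcript length in the ribosomal, proteasome, chromatin and autism risk differences was therefore not tested.

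**Figure D4:**
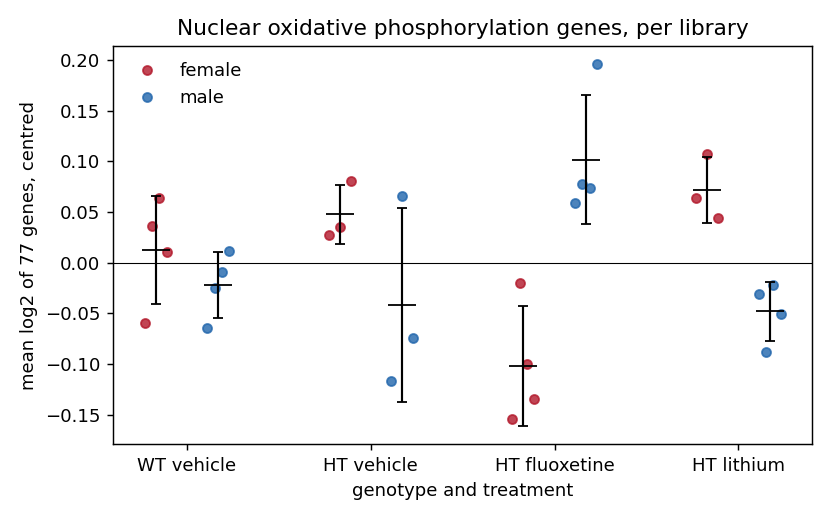
Mean log2 value of 77 nuclear oxidative phosphorylation genes in each library, centred on all libraries, by genotype and treatment, with females in red and males in blue and bars for the mean and SD. HT fluoxetine females average -0.10 and HT fluoxetine males 0.10.

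Within each sex limma and edgeR called no gene for lithium, while DESeq2 called genes in males. In females limma called 0 genes (768 at an unadjusted p under 0.05; edgeR 0, DESeq2 0), with mt-Nd6 at 0.70 ± 0.174 (adjusted p = 0.996). In males limma called 0 genes (1796 at an unadjusted p under 0.05; edgeR 0, DESeq2 18 higher and 5 lower), with Nostrin first (0.89 ± 0.161, adjusted p = 0.166). The female minus male test called 0 genes (limma; 523 at an unadjusted p under 0.05; edgeR 0, DESeq2 0). In males the chaperone list was higher (median 0.13, 29 of 31 positive, camera adjusted p = 4.12e-13; adjusted p = 0.324 with an estimated correlation), with 14 members higher adjusted over the list alone. Immediate early genes were lower in males (median -0.22, 25 of 33 negative, adjusted p = 2.73e-05; adjusted p = 0.822 with an estimated correlation). Olfactory markers were lower in the same comparison (median -1.49, adjusted p = 0.000403; adjusted p = 0.822 with an estimated correlation), and with the marker covariates the immediate early median was -0.062 (adjusted p = 0.00404) and 3 lists were called instead of 11. Fos (-0.63 ± 0.150) and Ier2 (-0.58 ± 0.142) were among 12 members lower adjusted over the list alone, and Homer1 (0.30 ± 0.073) was among 2 higher. In females the myelin genes were higher (median 0.27, adjusted p = 1.72e-06; adjusted p = 0.868 with an estimated correlation). That call was lost without HT vehicle female 3 (median 0.068, adjusted p = 0.344), whose myelin mean was -0.62. Striatal markers stood at 0.85 in HT lithium female 2 and below 0 in all 3 HT vehicle females, and with the marker covariates the myelin median was 0.17 (adjusted p = 0.000256).

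Female and male WT vehicle mice were compared as a reference for the sex differences. Of 45 genes called, 31 were higher and 14 lower in females (limma, n = 4 and 4; edgeR 21 and 14, DESeq2 264 and 96). The X chromosome held 4 of the higher genes and the Y chromosome 6 of the lower ones, leaving 27 and 8 elsewhere. Eif2s3x, an X-linked translation factor gene that escapes inactivation, was 1.46-fold higher (0.54 ± 0.041 SE, adjusted p = 9.07e-10). Prr5, a gene of the mTOR pathway, was 1.71-fold higher (0.78 ± 0.119, adjusted p = 0.00131), at 178 ± 14.0 (SD) in females and 105 ± 24.0 (SD) in males. The Prr5 call was lost without the libraries with high markers and when only the compared groups were fitted (adjusted p up to 0.128). The count was 1207 without WT vehicle male 4 and 17 without WT vehicle male 2. It was also lower with the marker covariates and without the libraries with high markers. Olfactory means lay from 0.71 to 1.72 in the WT males and from -1.46 to 1 in the WT females. Striatal means were 1.09 and 0.74 in WT vehicle females 1 and 3, and from -0.6 to -0.42 in the males.

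**Figure D5:**
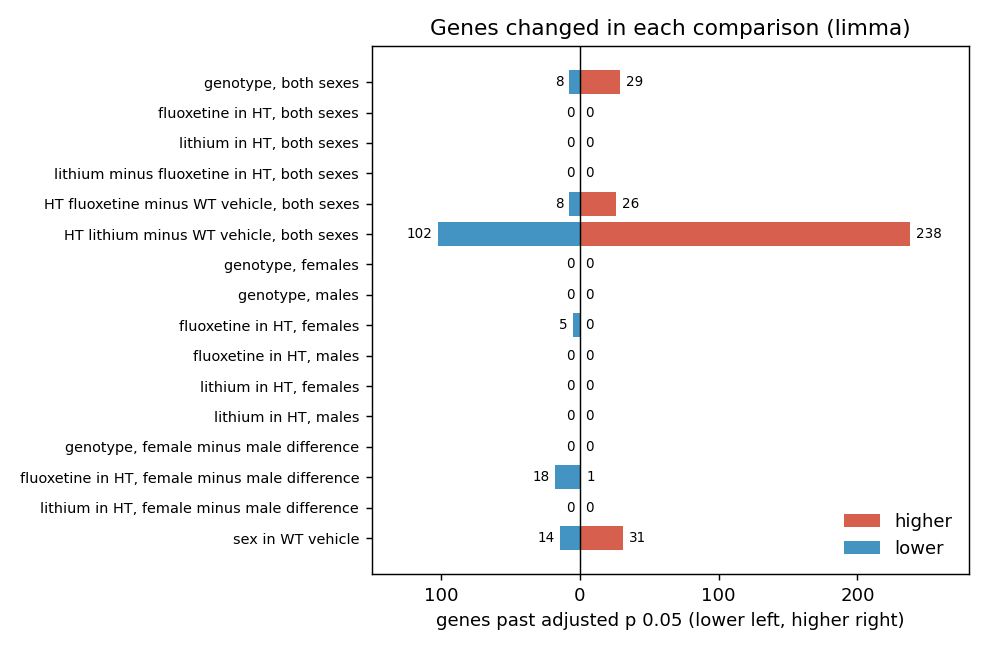
Number of genes past an adjusted p of 0.05 in each comparison (limma), with higher genes to the right and lower genes to the left. HT lithium against WT vehicle has 238 and 102, the genotype comparison 29 and 8, and fluoxetine and lithium against vehicle 0.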

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

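The tests weighed here that were chosen after the result was seen are the marker covariates, the immediate early genes beside the clock list and the chromosome 2 window. The other tests were fixed before their values were computed.

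The female minus male difference of fluoxetine was picked out because 19 genes differed between the sexes in their response, with lower oxidative phosphorylation genes. These transcripts are short, with a median length of 1141 bases against 3175 for all tested genes. Random lists matched on length, GC content and abundance had a median of -0.14, from -0.20 to -0.092, and 0 of 1000 were as low as the list itself at -0.26. The pool left out ribosomal and proteasome genes, which were also lower, and mitochondrially encoded genes. Genes drawn at random need not vary together as those of the list do, so the 0 of 1000 overstates the contrast. Short transcripts as a class could therefore account for part of the difference, and the test leaves open how much. With the olfactory and striatal marker means as covariates the list median was -0.259. This argues against these tissues as an account of it, only as far as the marker means follow them linearly. Meningeal, choroid plexus and thalamic tissue were not tested in this way and stay open. A single library is excluded as an account of the list median by the value nearest 0, which was -0.235 without HT vehicle male 1. This does not cover the count of 19 genes, which was 4 without HT vehicle female 3 and 50 without HT fluoxetine female 2. A sex-dependent response to fluoxetine remains a hypothesis for the rest. Of 100 splits of the libraries, 3 gave as many genes, whereas 74 gave as many called lists as the real 9.

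The clock list was higher in HT than in WT vehicle mice, with a median of 0.091. Collection at another time of day could do this, and would lower Arntl, Npas2 and Clock, whose median was -0.004 while the genes of the Per phase had 0.18, which leaves the point open. Higher neuronal activity is not excluded, since immediate early genes outside the clock list had a median of 0.054. The call on all 33 (adjusted p = 0.0444; adjusted p = 0.781 with an estimated correlation) was lost with the marker covariates (0.0989) and without any 1 of 8 libraries, such as HT vehicle male 2 (0.326). Against WT the clock median was also 0.095 in HT fluoxetine and 0.119 in HT lithium, where immediate early genes had -0.006 and 0.003, so the 2 lists did not move together there. With the olfactory and striatal marker means as covariates the median was 0.088. This argues against these tissues only as far as the marker means follow them linearly. Meningeal, choroid plexus and thalamic tissue were not tested in this way and stay open. An effect of genotype on clock genes was not told apart from time of day or activity.

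A processed pseudogene on chromosome 2 (Gm13736, 87526145 to 87526397, GRCm38), singled out after its values were seen, had at least 8 reads in all 21 HT libraries and 0 in 6 of 8 WT libraries. It rose by 3.29 ± 0.498 (SE; limma adjusted p = 0.00484). WT vehicle male 2 had 18 reads and WT vehicle female 3 had 6. A mislabelled library is excluded for male 2, left out when the genotype genes were chosen. Its mean over them was -0.18, inside the range of the other WT libraries (-0.37 to -0.10) and below that of HT vehicle (0.049 to 0.24). Those libraries chose the genes, but the lowest HT library given a drug, at -0.067, also lay above male 2. The mean of female 3 was -0.222, which does not test its label, since female 3 was among the libraries that chose the genes. A donor strain segment around Tbr1 could account for it. Within 50 Mb of Tbr1 14 of 627 genes were called for HT minus WT over all treatments, 2.23% against 1.91% elsewhere (Fisher one-sided exact p = 0.319), which leaves that open.

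Other splits of the same libraries were fitted for each comparison. They stayed within each sex, except for sex in WT, where females and males were exchanged. For genotype 1 of 100 splits, the real one, gave as many as 37 genes (highest other 2), a share under 0.05. For lists 27 of 100 gave as many as 14 (highest other 22), and chance is not excluded. The share for gene counts was also under 0.05 for HT fluoxetine against WT (2 of 100, real 34, highest other 1103). For HT lithium against WT it was 3 of 100 (real 340, highest other 651). The same holds for the female minus male fluoxetine difference (3 of 100, real 19, highest other 77) and sex in WT (1 of 35, real 45, highest other 11). These shares were not adjusted over the comparisons. By themselves they do not exclude chance, least of all where another split called more genes than the real one. The split with 1103 genes exchanged HT fluoxetine females 1, 3 and 4 with WT vehicle females 1, 3 and 4, besides 1 male of each group. It mostly turned the real female grouping around. It also placed HT fluoxetine female 2, with striatal markers at 1.77, beside WT vehicle females 1 and 3 (1.09 and 0.74). The females set against them lay at -0.3 or lower, so a structure by tissue was not told apart from the turned grouping. The split with 77 genes exchanged HT fluoxetine females 2 to 4 with all 3 HT vehicle females. It turned the real female grouping around, with HT fluoxetine female 1 placed among the vehicle females, so it does not by itself point to a structure. The split with 651 genes, where HT lithium female 1 and WT vehicle female 4 exchanged groups, also exceeds its real count. Chance is not excluded for the 5 genes of fluoxetine in females (2 of 35, highest other 91). The split with 91 genes made the same exchange of females as that with 77. Chance is not excluded for the lists of fluoxetine (85 of 100; real 8, highest other 21), lithium (62 of 100; 9, 19), HT fluoxetine against WT (32 of 100; 15, 21), HT lithium against WT (9 of 100; 18, 20) and the female minus male fluoxetine difference (74 of 100; 9, 22).

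With a real count of 0, where limma called no gene, every split gave as many: fluoxetine (100 of 100; highest other 7), lithium (100 of 100; 1), lithium minus fluoxetine (100 of 100; 5), and the female minus male difference of genotype (100 of 100; 191) and of lithium (100 of 100; 1). Within a sex this held for genotype in females (35 of 35; 2) and in males (35 of 35; 486), fluoxetine in males (35 of 35; 3) and lithium in males (35 of 35; 2). At an unadjusted p under 0.05 these comparisons had 1397, 2030, 626, 1001, 523, 1333, 1990, 1788 and 1796 genes, edgeR called 0 in each and DESeq2 6, 32, 2, 1, 0, 34, 36, 1 and 23. The 486 genes arose when HT vehicle male 2 and WT vehicle male 4 exchanged groups, and point to a structure of the samples. The split with 191 genes exchanged all 3 HT vehicle males with WT vehicle males 1 to 3, besides 1 female of each group. It mostly turned the real male grouping around, so it does not by itself point to a structure. For lithium in females the 10 splits are too few for a share under 0.05 (real 0, highest other 0; limma, 768 at an unadjusted p under 0.05, edgeR 0, DESeq2 0).

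Single libraries far from the other 3 of their group, by Dixon's ratio, numbered 21 of 305 values tested, where 15 are expected by chance. In HT fluoxetine female 1 the mean log2 value was -0.24 for cholesterol synthesis (others -0.01 to 0.02), 0.25 for interferon genes (-0.07 to -0.04) and -0.15 for layer 5 markers (0.06 to 0.09), and Rrp9 was at 454.9 (438.2 to 440.4). HT fluoxetine female 2 had striatal markers at 1.77 (-0.52 to -0.3), and HT fluoxetine female 4 clock genes at 0.12 (0.01 to 0.02) and Tgfbr2 at 475 (519.3 to 527). HT fluoxetine male 3 had microglia markers at 0.13 (-0.01) and Decr1 at 409.6 (363.9 to 366.1), and HT fluoxetine male 4 oxidative phosphorylation genes at 0.2 (0.06 to 0.08). HT lithium male 1 had Dpysl4 at 1707 (1827.2 to 1843.7), male 2 striatal markers at 0.53 (-0.42 to -0.28) and male 3 Tlr3 at 228.8 (254.3 to 258.9). WT vehicle female 1 had Dpysl4 at 1716.2 (1873.8 to 1883.9), female 3 serotonin genes at 0.21 (0.01 to 0.03) and female 4 chaperone genes at 0.05 (-0.03 to -0.02). WT vehicle male 1 had endothelial markers at 0.2 (-0.05 to -0.03), male 2 precursor markers at -0.14 (0.06 to 0.09), male 3 olfactory markers at 1.72 (0.71 to 0.86) and Lrrtm1 at 1030.7 (1174.2 to 1198.8), and male 4 Decr1 at 334.4 (379.7 to 388.9).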

How the results depend on the processing

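The settings chosen after results were seen were edgeR, DESeq2, the marker covariates and the fit without the 8 libraries with high olfactory or striatal markers. Gene counts stayed within 1.5 times in 381 of 464 fits without 1 library and 202 of 278 other fits. List medians kept direction and call in 4509 of 4843 and 700 of 1169, with 334 and 455 calls weaker, and named genes in 3432 of 3625 and 2030 of 2185. Depth limits genes with few reads, and except where named below, the cause of a shift was not tested.

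Genotype gave 63 genes with a filter at 50 (fewer genes tested), 8 with only the compared groups (fewer samples), 99 with library weights, 82 with the replicate number as a block, 73 with the library number as a block, 18 with additive sex, 167 at an adjusted p under 0.1, 142 with marker covariates, 6 without the libraries with high markers and 212 with DESeq2. In the same order of settings, where the count moved, HT fluoxetine against WT gave 0 with only the compared groups, 95 with weights, 63 and 68 with the blocks, 87 at 0.1, 92 with covariates, 5 without those libraries and 96 with DESeq2. That 0 is limma's, with 1655 at an unadjusted p under 0.05 in the fit of all groups, where edgeR gave 32. HT lithium against WT gave 1174 with weights, 540 with the library number block, 790 at 0.1, 177 with covariates, 42 without those libraries and 588 with DESeq2.

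Fluoxetine gave 1 gene without the libraries with high markers and 6 with DESeq2, lithium 13 with weights, 1 with the library number block and 32 with DESeq2, and lithium minus fluoxetine 1 without those libraries and 2 with DESeq2. Genotype in females gave 2 with only the compared groups, 22 with weights, 3 with the replicate block and 34 with DESeq2, and in males 1, 5 with weights, 2 with the library number block, 1 at 0.1, 2 with covariates and 36 with DESeq2. Fluoxetine in females gave 11 with quantile normalisation, 21 with median ratios, 2 without a trend, 8 with a pseudocount of 0.5, 21 without a filter, 19 with a filter at 50, 1 with only the compared groups, 128 with weights, 2 and 1 with the blocks, 30 at 0.1, 2 without those libraries, 8 with edgeR and 138 with DESeq2. Fluoxetine in males gave 1 with DESeq2, and lithium in males 1 with only the compared groups and 23 with DESeq2. The female minus male difference gave 1 with DESeq2 for genotype and 1 with only the compared groups for lithium. For fluoxetine it gave 1 with only the compared groups, 9 with the library number block, 78 at 0.1, 40 with covariates, 71 without those libraries and 198 with DESeq2. Sex in WT gave 81 with quantile normalisation, 29 without a trend, 99 with a filter at 50, 19 with only the compared groups, 697 with weights, 70 with the replicate block, 349 at 0.1, 27 with covariates, 11 without those libraries and 360 with DESeq2. Replicate numbers were not taken as pairs, since in no comparison was every pair's correlation over 0.1 (from -0.202 to 0.23). Of 29 libraries, 14 correlated best with their own number. The share that would do so without any pairing was not computed, so this count is no reason against pairing. Genotype over both sexes gave more genes with either number as a block, as listed above. An effect shared by libraries of the same number therefore stays open.

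Lists called by camera fell to 0 for genotype, fluoxetine and lithium with an estimated correlation, and to 2, 0 and 1 with fry. With covariates there were 3 for fluoxetine and 2 for lithium, and without the libraries with high markers 5 and 4. The correlations across genes with divided HT vehicle libraries were -0.018, 0.017 (reversed) and 0.096.

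With marker covariates these medians reversed: fluoxetine layer 6 -0.062, myelin -0.046 and striatal -0.018; lithium cholesterol -0.006; HT fluoxetine against WT striatal -0.024 and olfactory 0.029. Within a sex they were 0.003 for striatal markers in females by genotype, and in males with fluoxetine -0.046 for layer 6, -0.181 for myelin (called lower, adjusted p = 0.00118, the 1 call among these reversals), -0.04 for striatal markers and -0.008 for cholesterol. The female minus male genotype difference gave 0.078 for striatal markers. Without the libraries with high markers, cholesterol in lithium minus fluoxetine was -0.029 and striatal markers in females by genotype 0.026. Tbr1 under a drug, never called, reversed for fluoxetine to -0.006 with the replicate block, -0.021 and -0.014 without HT fluoxetine females 2 and 4, -0.011 and -0.003 without HT vehicle female 3 and male 1, and -0.07 with covariates, the highest value being 0.102. For lithium it was -0.008 with covariates. For fluoxetine in females Tbr1 was 0.113 and 0.037 without HT fluoxetine female 1 and HT vehicle female 1 and 0.06 without the libraries with high markers, the lowest being -0.133, and in males -0.05 with covariates. For lithium in females it was -0.003 and -0.022 without HT lithium female 2 and HT vehicle female 3, -0.036 with covariates and -0.003 without those libraries, the highest being 0.129.

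Without 1 library the counts ranged from 2 to 176 (genotype), 0 to 1 (fluoxetine), 0 to 0 (lithium), 0 to 1 (lithium minus fluoxetine), 10 to 98 (HT fluoxetine against WT), 85 to 722 (HT lithium against WT), 0 to 6 and 0 to 2.3e+02 (genotype in females and males, the latter rounded), 0 to 87 and 0 to 0 (fluoxetine), 0 to 0 and 0 to 1 (lithium), 0 to 0, 4 to 50 and 0 to 0 (female minus male for genotype, fluoxetine, lithium) and 17 to 1207 (sex in WT). Lists ranged from 11 to 16, 5 to 10 and 3 to 14, and correlations from -0.606 to -0.582, -0.515 to -0.467 and 0.627 to 0.684.

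The libraries that moved a count by more than 1.5 times follow, with G for genotype, F for fluoxetine, L for lithium, f and m for a sex, W for against WT, D for the female minus male fluoxetine difference and S for sex in WT. HT vehicle: female 1 G 2, Ff 2; female 2 Gf 6, Ff 9, D 37; female 3 G 5, Ff 0, D 4; male 1 G 12, D 5; male 2 G 153, FW 54, Gm 12, Ff 8, D 49; male 3 G 5, D 11, S 79. WT vehicle: female 1 G 17, LW 225, Gf 3, Ff 11, S 25, female 2 G 11, FW 11, LW 176, Ff 2, S 23, female 3 G 19, FW 20, LW 177, S 70, female 4 FW 61, Lm 1, S 18, male 1 G 21, FW 21, LW 165, S 22, male 2 Gf 2, Gm 1, S 17, male 3 G 21, LW 171, Gm 1, Ff 9, S 20, male 4 G 176, FW 60, LW 722, Gm 2.3e+02, Ff 19, S 1207. HT fluoxetine: female 1 G 58, FW 98, LW 534, Gm 2, Ff 87, S 157, female 2 F 1, L minus F 1, D 50, female 3 F 1, Ff 1, D 11, female 4 FW 10, Ff 0, D 9, male 1 Ff 8, D 29, male 2 G 22, FW 19, D 11, male 4 Ff 28, D 9. HT lithium: female 1 Ff 2, female 2 LW 199, Gf 1, female 3 LW 85, male 2 Lm 1, male 3 LW 175, male 4 LW 198, Ff 1.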

Other observations

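The hypotheses and the tests of them stand with the results above, and none is added here. Some groups of genes called in the genotype comparison within females were not described above. Myelin genes were negative in 27 of 28 in HT against WT vehicle females (median -0.36, camera adjusted p = 2.1e-09; adjusted p = 0.585 with an estimated correlation). The striatal marker mean was 1.09 and 0.74 in WT vehicle females 1 and 3 and below 0 in all 3 HT vehicle females, and HT vehicle female 3 had the lowest myelin mean (-0.62). The myelin median was -0.17 with the olfactory and striatal marker means as covariates (adjusted p = 0.000489) and -0.16 without HT vehicle female 3 (adjusted p = 0.0095). Markers of oligodendrocyte precursors were negative in 14 of 16 (median -0.18, adjusted p = 3.54e-06; adjusted p = 0.0584 with an estimated correlation), led by the growth factor receptor gene Pdgfra (-0.27 ± 0.082, SE). Serotonin receptor and transport genes were negative in 15 of 18 (median -0.094, adjusted p = 0.00639; adjusted p = 0.0584 with an estimated correlation), led by Htr2c (-0.69 ± 0.188). In males the presynaptic vesicle genes were positive in 34 of 40 (median 0.10, adjusted p = 0.000982; adjusted p = 0.587 with an estimated correlation), with the calcium sensor gene Syt7 at 0.17 ± 0.057. That call was lost without HT vehicle male 3 (median 0.048, adjusted p = 0.168). The olfactory marker mean was 1.029 in WT and 0.521 in HT vehicle males, and the presynaptic median was 0.068 with both marker means as covariates (adjusted p = 0.00375) and 0.061 without the libraries with high markers (adjusted p = 0.0101). Ribosomal protein genes were negative in 66 of 80 in males (median -0.089, adjusted p = 2.34e-09; adjusted p = 0.576 with an estimated correlation), with 8 lower adjusted over the list alone, among them Rpl22 (-0.22 ± 0.054).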
